A study of Rattus norvegicus with 8 samples.

How the data were processed

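The series holds 8 samples of rat small intestine, 4 labelled CF and 4 labelled WT, all Sprague Dawley at postnatal day 21 per the labels. The protocol in the labels describes trimming of the whole small intestine, a flush with buffered saline and dithiothreitol, opening of the tissue, Trizol extraction and stranded mRNA sequencing on a HiSeq2500. The flush was meant to remove mucus and digesta. Per the submitters' processing notes, bcl2fastq, cutadapt, STAR 2.3.1z, StringTie and Cuffdiff were used with genome build Rnor_6.0. Their order, settings and filters are not given in the sources used here.

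The estimated counts are the raw fragments per locus and library of the Cuffdiff gene table, as deposited by the authors and before scaling between libraries, per the file headers. Of these values 5.99% were fractional, and all were rounded for the main test. The FPKM values, per library and per group, were made by the authors with Cuffdiff, after its scaling between libraries and by transcript length, per the file headers. They were used only for 2 alternatives and for the authors' group values of Cftr. 2 further columns of per-library values were not used here. Coordinates are 1-based spans in Rnor_6.0 as the table gives them. Such a span covers a bundle of overlapping transcripts and can include neighbouring genes. Gene names came from the table, with a RefSeq table of another build used for synonyms only.

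The table names each library by its condition and a number from 0 to 3, while the sample titles are numbered from 1 to 4. The group of each library is therefore known, but not which title it carries. Within a group each library was tied to a title only as a placeholder, and no result uses that tie. The assignment of placeholders was changed once during the work, and all results were the same before and after. The labels give no sex, CF allele, litter or batch.

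Loci were kept by edgeR's filterByExpr with the group (minimum count 10, minimum total 15), which left 16941 of 52753 loci, 13728 of them with a single gene symbol. Libraries were scaled by TMM, and CF was compared with WT by edgeR's robust quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were derived from the same test, as the fold change over the square root of its F statistic. Cftr was also tested by an exact permutation test over the 70 assignments of the 8 libraries. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

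The test was tried on simulated counts at 16567 loci. It recovered 14.9% of loci changed 1.5-fold, 64.2% of those changed 2-fold and 98.5% of those changed 4-fold, and 13 of its 131 calls (9.92%) were false, above the nominal 5%. Changes of 1.5-fold were therefore mostly missed at this number of libraries.

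Gene lists were fixed before the data were seen. They numbered 35 with 715 entries, of which 557 entries (541 genes) were tested. Members were matched by symbol, 2 of them by a synonym in the RefSeq table (Muc2 and Nupr1), and 23 entries found only in loci with several symbols were left out. Lists with at least 3 tested members, 33 in all, were tested by camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and by fry. The sex check list was not tested. Its 5 Y-linked loci had 1 to 10 fragments per library in all 8 libraries, so these loci showed no split by sex. Counts this low cannot tell libraries of 1 sex from loci that were hardly counted. The list of stomach genes had fewer than 3 tested members. The score of a list in a library is the mean of its members' log2 CPM after the mean of each gene over the 8 libraries was subtracted. A count over the list alone used p-values adjusted within that list.

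The named genes followed a fixed rule: Cftr, up to 12 rises and 12 falls with the largest log2 fold changes, up to 4 called members of each list with any, and the 2 most abundant members of each other list. The rises and falls were taken from called loci with 1 gene symbol, a mean of at least 1 CPM and groups that did not overlap. Placeholder symbols, such as names that start with LOC, were left out. The rule gave 74 genes, with 20 rises and 2 falls meeting it. A further 52 genes and loci were chosen after their values were seen. Some genes that these choices gave are not reported here. Alternatives changed the scaling, the low-count filter, the test, the unit, the rounding, the threshold, the set test and the libraries used. Some gene families have near-identical members (Defa, Hba and Hbb, Mcpt, Klk1c, Reg3), and fragments could have been shared between them.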

Results

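Gene expression was measured by stranded mRNA sequencing of small intestine, taken over its whole length, from Sprague Dawley rats at postnatal day 21. The series compares 4 libraries from rats with cystic fibrosis (CF), the inherited disease caused by loss of the chloride and bicarbonate channel CFTR, with 4 libraries from wild-type (WT) rats. The deposited tables hold 52753 loci, and 40072 of them had at least 1 fragment. The CF libraries held 20.5, 19.5, 18.6 and 20.9 M assigned fragments in CF libraries 0, 1, 2 and 3. The WT libraries held 15.3, 19.2, 20.8 and 15.3 M in the same order. The libraries carry numbers from 0 to 3 within each group, and these numbers only name them. The labels do not say whether each library came from its own animal, so p-values describe the spread between these libraries. Values are given as CPM (counts scaled to library size), mean ± SD of 4 libraries per group, and fold changes are CF over WT on the log2 scale with their standard errors (SE).

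The comparison asks how the small intestine of rats with CF differs from that of WT rats. Cftr itself (chromosome 4, 42692836 to 42860679, Rnor_6.0) did not differ detectably in transcript level. It was at 97.3 ± 6.40 CPM in CF and 94.8 ± 14.7 CPM in WT, with library values from 92.0 to 107 CPM in CF and from 74.0 to 107 CPM in WT. The log2 fold change was 0.04 (SE 0.12, 95% interval −0.20 to 0.28), and a two-sided exact permutation test gave p = 0.8286, where the smallest p that 4 against 4 allows is 0.0286. The authors' group FPKM values were 11.7 in CF and 11.3 in WT. The labels do not give the CF allele, and counts per locus cannot show a small deletion or insertion, so this level does not check the labels.

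The libraries of the 2 groups were similar over the transcriptome, with Pearson correlations of log2 CPM across loci from 0.957 to 0.984 over all pairs. The first principal component held 31.3% of the variance and the second 19.5%. The 4 WT libraries lay between 18.9 and 28.6 on the first component, while the CF libraries were spread from −56.9 for CF library 0 and −43.6 for CF library 3 to 4.12 and 8.48 for CF libraries 1 and 2. CF library 0 also stood apart in its enterocyte genes. The 30 tested members of the digestion and absorption list lay on average 1.03 log2 units below their mean over all libraries there (score −1.03), against scores of 0.48, 0.16 and 0.13 in CF libraries 1, 2 and 3.

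**Figure D1:**
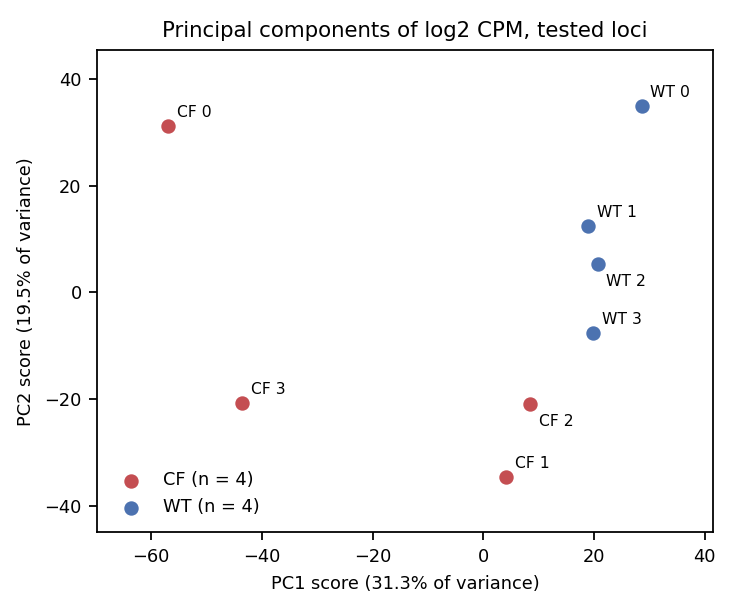
Scores of the 8 libraries on the first 2 principal components of log2 CPM over the 16941 tested loci, with CF in red and WT in blue. The WT libraries lie within 18.9 to 28.6 on the first component, and CF libraries 0 and 3 lie at −56.9 and −43.6.

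Transcripts of Cd55, Creb3l1, Junb and Rhof were higher in the CF intestine, and those of Asb15 were nearly absent. Cd55, which encodes the decay-accelerating factor that protects cells from complement, rose 4.27-fold from 52.0 ± 8.52 CPM in WT to 222 ± 37.2 CPM in CF. Creb3l1, a membrane-bound transcription factor of secretory cells, rose 2.32-fold to 188 ± 21.7 CPM. Junb, a subunit of the AP-1 transcription factor, rose 2.20-fold to 88.3 ± 9.50 CPM, and Rhof, which encodes a small GTPase, rose 2.06-fold to 79.1 ± 8.20 CPM. In the other direction Asb15, a substrate adaptor of a ubiquitin ligase, fell from 7.50 ± 1.15 CPM in WT to 0.186 ± 0.109 CPM in CF. These 5 genes passed the test with all 8 libraries and with any 1 library left out. Their log2 fold changes were 2.09 (SE 0.16) for Cd55, 1.21 (SE 0.11) for Creb3l1, 1.14 (SE 0.10) for Junb, 1.05 (SE 0.10) for Rhof and −5.31 (SE 0.35) for Asb15. Their adjusted p-values, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, were 0.000482, 0.00147, 0.00147, 0.00265 and 0.000306. On the authors' FPKM values with limma, Cd55 kept its call. The others lost theirs on log2(FPKM + 0.1), with adjusted p-values of 0.120 for Creb3l1, 0.113 for Junb, 0.106 for Rhof and 0.0661 for Asb15, and on log2(FPKM + 1) Creb3l1 (0.133), Junb (0.130) and Rhof (0.112) did so too.

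**Figure D2:**
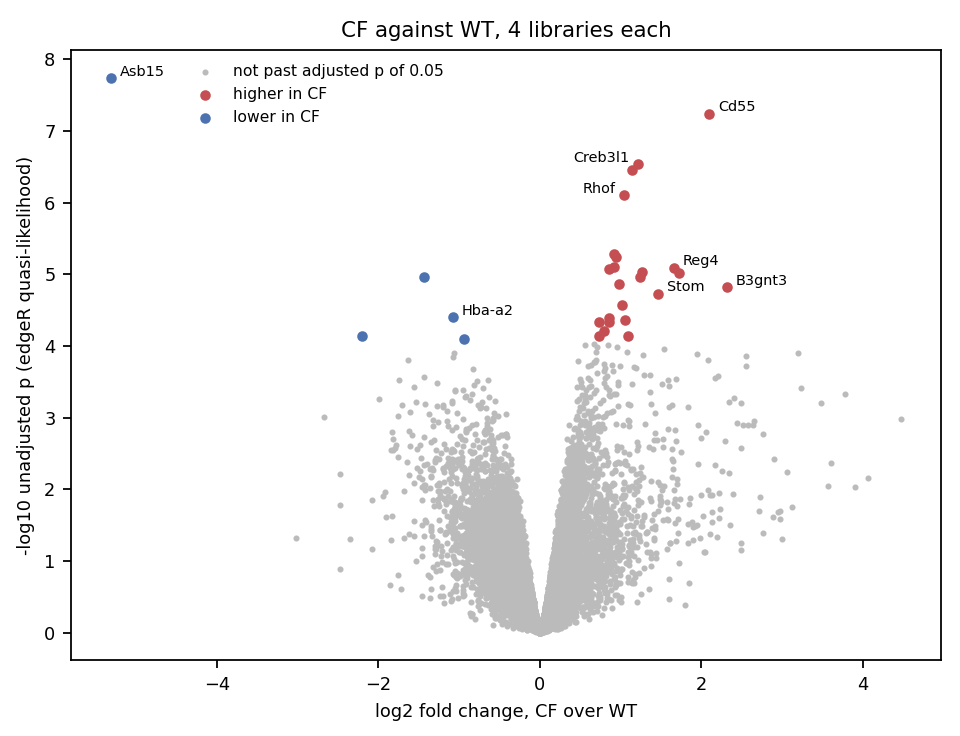
Log2 fold change of CF over WT (x axis) against −log10 of the unadjusted p from edgeR's quasi-likelihood test (y axis) for the 16941 tested loci. The 23 loci higher in CF at an adjusted p under 0.05 are red and the 5 lower are blue.

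The other 8 rises named by rule were B3gnt3, Reg4, S100a6, Stom, Vip, Etv5, Avpi1 and Fam83e. B3gnt3 (chromosome 16, 20108364 to 20150943), which extends O-linked sugar chains, was at 8.48 ± 3.60 CPM in CF and 1.69 ± 0.210 CPM in WT, a log2 fold change of 2.32 (SE 0.31, adjusted p = 0.0159). Reg4, a secreted lectin of the regenerating family, was at 420.5 ± 101 CPM against 133 ± 30 CPM, a log2 fold change of 1.66 (SE 0.21, adjusted p = 0.0132). S100a6, a calcium-binding protein gene, had a log2 fold change of 1.72 (SE 0.21), and Stom, which encodes the membrane protein stomatin, one of 1.47 (SE 0.20). Vip, the vasoactive intestinal peptide of enteric neurons that drives epithelial secretion, rose from 22.5 ± 3.93 to 54.1 ± 9.66 CPM, a log2 fold change of 1.26 (SE 0.16, adjusted p = 0.0132). Of the 20 tested genes of enteric neurons, glia and interstitial cells it was the only one past the test, while 3 others had higher means in CF and 16 lower means. The ETS-family transcription factor gene Etv5 (log2 fold change 1.23), Avpi1 (1.06) and Fam83e (1.02) also rose. On log2(FPKM + 1) and log2(FPKM + 0.1) calls were lost for B3gnt3 (adjusted p = 0.197 and 0.158), Etv5 (0.173 and 0.158), Avpi1 (0.293 and 0.274) and Fam83e (0.173 and 0.158), and on the latter for Vip (0.0507). With limma-voom B3gnt3 and Avpi1 lost theirs (0.0665 each). With 1 library left out in turn, the log2 fold change was 2.09 to 2.50 for B3gnt3 and 1.53 to 1.83 for Reg4. It was 1.49 to 1.87 for S100a6, 1.23 to 1.61 for Stom and 1.13 to 1.35 for Vip. For Etv5 it was 1.14 to 1.34, for Avpi1 0.97 to 1.20 and for Fam83e 0.88 to 1.09. Each of these 8 rises lost its call without WT library 1, 2 or 3, where 5, 5 and 6 loci were called in all. The adjusted p-values in that order were 0.119, 0.0752 and 0.0940 for B3gnt3, 0.0923, 0.0752 and 0.0809 for Reg4, 0.0923, 0.0818 and 0.0733 for S100a6, and 0.119, 0.101 and 0.0940 for Stom. They were 0.0622, 0.0752 and 0.0518 for Vip, 0.0981, 0.0752 and 0.0641 for Etv5, 0.185, 0.157 and 0.0940 for Avpi1, and 0.119, 0.147 and 0.0940 for Fam83e. Without WT library 0 calls were lost for B3gnt3 (0.0568), Stom (0.0740), Avpi1 (0.0920) and Fam83e (0.0758), and Avpi1 also lost its call without CF library 1 (0.0626) or 3 (0.114). Smaller rises included the sialyltransferase gene St6galnac6 (log2 fold change 0.98). They also included Phlda2 (0.85), Tmem150b (0.95), Plp2 (0.80) and the kallikrein gene Klk1c9 (0.91). Klk1c9 has close paralogs whose fragments the counting could have shared. These 5 were named after their values were seen, and none kept its call with every library left out in turn. Without WT library 1 the adjusted p was 0.185 for Plp2 and 0.0814 for each of the other 4. Without WT library 2 it was 0.0752 for St6galnac6 and Klk1c9, 0.0715 for Phlda2, 0.0655 for Tmem150b and 0.187 for Plp2. Without WT library 3 it was 0.0733 for St6galnac6, 0.0540 for Phlda2, 0.0641 for Tmem150b and 0.105 for Plp2, which also lost its call without CF library 3 (0.114) or WT library 0 (0.0758). Over all alternative fits, these removals included, calls were lost in 7 for St6galnac6 and 7 for Phlda2. They were lost in 5 for Tmem150b, 11 for Plp2 and 6 for Klk1c9.

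**Figure D3:**
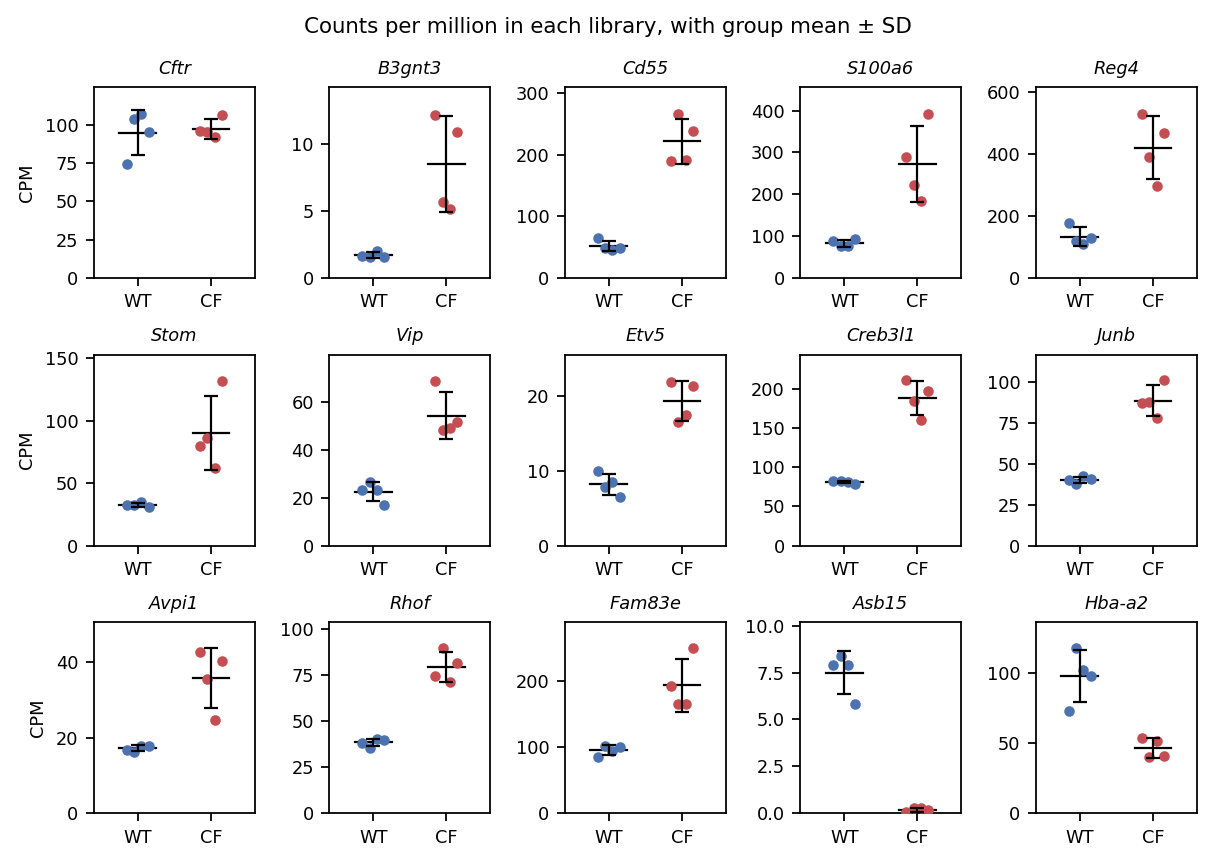
CPM of Cftr and of the 14 genes with the largest rises and falls that met the naming rule, 1 point per library with group mean and SD (n = 4 each, linear axes from 0). Cftr overlaps between the groups, while in the other 14 panels all 4 CF libraries lie on one side of all 4 WT libraries.

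The 5 falls were Asb15, the hemoglobin gene Hba-a2 and 3 loci without a gene name. Asb15 (chromosome 4, 51614676 to 51644492) lies 8.75 Mb from Cftr and had 14 fragments over the 4 CF libraries against 552 over the 4 WT libraries. Hba-a2 was at 46.4 ± 7.21 CPM in CF and 97.8 ± 18.7 CPM in WT, a log2 fold change of −1.07 (SE 0.16, adjusted p = 0.0339). It lost its call without CF library 1 (adjusted p = 0.0681) or 3 (0.116) and without WT library 1 (0.147), 2 (0.147) or 3 (0.0940). It also lost it with limma-voom (0.0535) and on log2(FPKM + 1) (0.277) and log2(FPKM + 0.1) (0.268). Its fragments could be shared with the near-identical copies of the alpha-globin cluster. The unnamed loci, named here after their values were seen, were XLOC_033648 (chromosome 4, 67579661 to 67587029), XLOC_021157 (chromosome 17, 43567528 to 43609700) and XLOC_028846 (chromosome 20, 18374853 to 18381347). They had log2 fold changes of −1.43 (SE 0.18), −2.20 (SE 0.35) and −0.94 (SE 0.15). XLOC_033648 lost its call without WT library 1 (adjusted p = 0.0814), 2 (0.0655) or 3 (0.0733). XLOC_021157 lost its call without CF library 2 (0.0567) or 3 (0.157) and without WT library 0 (0.0959), 1 (0.185), 2 (0.176) or 3 (0.0809). XLOC_028846 lost its call without CF library 1 (0.0813), 2 (0.0596) or 3 (0.157) and without WT library 0 (0.0959), 1 (0.205), 2 (0.176) or 3 (0.101). Over all alternative fits, these removals included, calls were lost in 6 for XLOC_033648, 9 for XLOC_021157 and 10 for XLOC_028846.

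In all, 28 of 16941 tested loci passed an adjusted p of 0.05, 23 higher and 5 lower in CF, and in all 28 the groups did not overlap. Groups did not overlap in 8.78% of tested loci, where chance gives 2.86%. At an unadjusted p of 0.05, 2566 loci passed, where 847 would by chance. Both chance figures are averages, which loci that vary together can exceed in a single grouping. Neither count was made for other splits of the libraries. The count was sensitive to the libraries, to the low-count filter and to the test. It was 136 without CF library 0, 77 without CF library 2, 5 without WT library 1, 5 without WT library 2 and 6 without WT library 3. With no low-count filter edgeR called 553 of 40061 loci. DESeq2, which tested 40004 loci without the main filter, called 566, among them all 28. On the 16941 loci of the main test limma-voom called 17. Of the 14 named rises and falls, 9 lost their call when 1 of 6 libraries was left out, with adjusted p-values of up to 0.185. Leaving out CF library 1 or CF library 3 ended 2 of these calls each, WT library 0 ended 4, and each of WT libraries 1, 2 and 3 ended 9.

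Most goblet cell and mucus genes had higher means in CF. Here and below the members past the test over a list alone were named after their values were seen. Of 18 tested members 15 had higher means in CF, 8 rose when adjusted over the list alone and 1, Creb3l1, passed over all loci. Spink4, a goblet cell secretory product, was at 389 ± 89.2 CPM against 86.3 ± 38.4 CPM, a log2 fold change of 2.17 (SE 0.38). The locus AABR07006030.1, a name that the reference table gives as a synonym of the mucin gene Muc2, was at 3801 ± 608 CPM against 2422 ± 314 CPM (log2 fold change 0.65, SE 0.18). Agr2, a disulfide isomerase needed for mucin folding, had a log2 fold change of 0.66 (SE 0.19). The secretory-lineage transcription factor genes Atoh1 and Spdef had log2 fold changes of 0.54 (SE 0.11) and 0.65 (SE 0.16). The list passed camera's test with a preset correlation (adjusted p = 1.66e-07), and its adjusted p = 0.419 with an estimated correlation. Of the 35 splits of the libraries, 2 gave a mean difference as large, the real one included. WT library 0 was low for this list, with a score of −0.64 against −0.25 to −0.01 in WT libraries 1, 2 and 3. CF library 0, at −0.05, lay inside the WT range, while CF libraries 1, 2 and 3 had scores of 0.33, 0.29 and 0.42.

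Most genes of cholesterol synthesis had higher means in CF. Of 23 tested members 22 had higher means in CF, 18 rose when adjusted over the list alone, and 2 passed over all loci. Those were Idi1, the isopentenyl diphosphate isomerase gene (107 ± 15.9 CPM against 58.8 ± 6.16 CPM, log2 fold change 0.86, SE 0.13, adjusted p = 0.0343), and the sterol demethylation gene Msmo1 (123 ± 18.5 CPM against 73.7 ± 3.67 CPM, log2 fold change 0.74, SE 0.12, adjusted p = 0.0457). Idi1 lost its call without CF library 3 (adjusted p = 0.113) and without WT library 0 (0.0920), 1 (0.149), 2 (0.131) or 3 (0.0940). Msmo1 lost its call without CF library 1 (0.0681), 2 (0.0529) or 3 (0.1002) and without WT library 0 (0.0966), 1 (0.206), 2 (0.187) or 3 (0.103). Over all alternative fits, these removals included, Idi1 lost its call in 11 and Msmo1 in 14. Among those past the test over the list alone were Cyp51 (log2 fold change 0.69), Mvd (0.71) and Insig1 (0.85). The list's adjusted p was 3.35e-15 with the preset correlation and the adjusted p = 0.379 with an estimated correlation. The mean of its members was highest in CF libraries 1, 2 and 3, with scores of 0.30, 0.38 and 0.40. CF library 0, which was low in enterocyte genes, had a score of −0.09, above the WT range of −0.26 to −0.22.

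Most immediate early and heat shock genes, fixed as a marker of tissue handling, also had higher means in CF. Of 17 tested members 16 had higher means in CF, 12 rose when adjusted over the list alone and 1, Junb, passed over all loci. The transcription factor genes Egr2, Nr4a1, Egr1 and Fos had log2 fold changes of 1.94 (SE 0.33), 1.20 (SE 0.22), 1.16 (SE 0.32) and 0.83 (SE 0.23), and the phosphatase gene Dusp1 one of 0.79 (SE 0.14). Hspb1 was the heat shock member past the test over the list alone (0.65, SE 0.21). The list's adjusted p was 1.46e-11 with the preset correlation and the adjusted p = 0.183 with an estimated correlation.

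Epithelial antimicrobial and inflammatory genes had higher means in CF for 14 of 15 tested members, and 3 rose when adjusted over the list alone. Duox2, the dual oxidase that releases hydrogen peroxide into the lumen, was at 158 ± 11.3 CPM against 48.8 ± 19.2 CPM (log2 fold change 1.69, SE 0.30). Its maturation factor gene Duoxa2 was at 44.4 ± 8.05 CPM against 9.63 ± 4.47 CPM (2.20, SE 0.37). The calgranulin gene S100a9 was at 6.70 ± 8.32 CPM against 0.390 ± 0.291 CPM, and its log2 fold change of 4.06 was 2.75 without CF library 0. It is also 1 of the 5 tested members of the neutrophil and eosinophil list, so it contributes to that list's scores. Those scores followed the same CF libraries (1.16 and 0.58 in CF libraries 0 and 3, −0.01 and 0.07 in CF libraries 1 and 2). Of the 5 members 3 had higher means in CF, and their median log2 fold change was 0.10. The most abundant members, Reg3g and Reg3b, varied widely, with Reg3g at 9961 ± 6567 CPM in CF and 3909 ± 2954 CPM in WT, and did not pass the test. The list's adjusted p was 1.19e-05 with the preset correlation and the adjusted p = 0.379 with an estimated correlation. Its score was 1.46 in CF library 0 and 0.95 in CF library 3 but 0.06 and 0.10 in CF libraries 1 and 2, and −1.35 in WT library 0 against −0.52 to −0.31 in the other WT libraries.

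Markers of blood were lower in CF, and those of vessels less clearly so. All 4 tested red cell genes had lower means, and 3 fell when adjusted over the list alone, namely the beta-globin gene Hbb (54.3 ± 8.86 CPM against 157 ± 64.4 CPM, log2 fold change −1.53), Alas2 (−1.09) and Slc4a1 (−1.31). Of 15 blood and lymph vessel genes 13 had lower means, and the endothelial genes Emcn, Kdr and Cdh5 fell when adjusted over the list alone (log2 fold changes −0.71, −0.68 and −0.61). The vessel score of CF library 0 was 0.19, inside the WT range of −0.10 to 0.25, and 4 of the 35 splits of the libraries, the real one included, gave a mean difference as large. Both lists had an adjusted p of 0.000203 with the preset correlation, and with an estimated correlation the adjusted p = 0.372 for blood and the adjusted p = 0.695 for vessels.

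The remaining lists that passed the preset test had few or no members past it alone. Smooth muscle genes had higher means in CF for 21 of 25 members, with Des (log2 fold change 0.97, SE 0.18) and Cnn1 (0.88, SE 0.19), which encode desmin and calponin, past the test over the list alone. The adjusted p was 0.000362 for smooth muscle, the adjusted p = 0.794 with an estimated correlation, and it was 0.0679 without WT library 3. No member passed the test over the list alone in 4 lists. Means were higher in CF for 18 of 20 genes of ER stress (adjusted p = 0.000717), 18 of 21 of proliferation (0.00235) and 15 of 18 of cell junctions (0.0160), and lower for 20 of 26 of extracellular matrix (0.00969). With an estimated correlation the adjusted p = 0.626 for ER stress, 0.794 for proliferation, 0.783 for cell junctions and 0.794 for extracellular matrix. Macrophage genes had lower means for 12 of 16 members (adjusted p = 0.0357, and adjusted p = 0.794 with an estimated correlation), and the growth factor receptor gene Csf1r fell over the list alone (−0.56, SE 0.14). The proliferation call was lost without CF library 0 (0.187), the extracellular matrix call without WT library 0 (0.0690) or WT library 2 (0.0890) and the junction call without CF library 1 (0.176) or WT library 2 (0.0997). The macrophage call was lost without CF library 1 (0.114), 2 (0.101) or 3 (0.0538) and without WT library 1 (0.105), 2 (0.197) or 3 (0.0654). In all, 12 of 33 tested lists passed with the preset correlation and none with an estimated one. Of the 35 splits of the 8 libraries into 4 and 4, 24 gave at least 12 lists, the real split included, so the number of lists called does not set CF apart from WT. Splits with a mean difference as large numbered 3 for smooth muscle, 3 for ER stress, 7 for cell junctions, 9 for proliferation, 15 for macrophages and 18 for extracellular matrix.

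**Figure D4:**
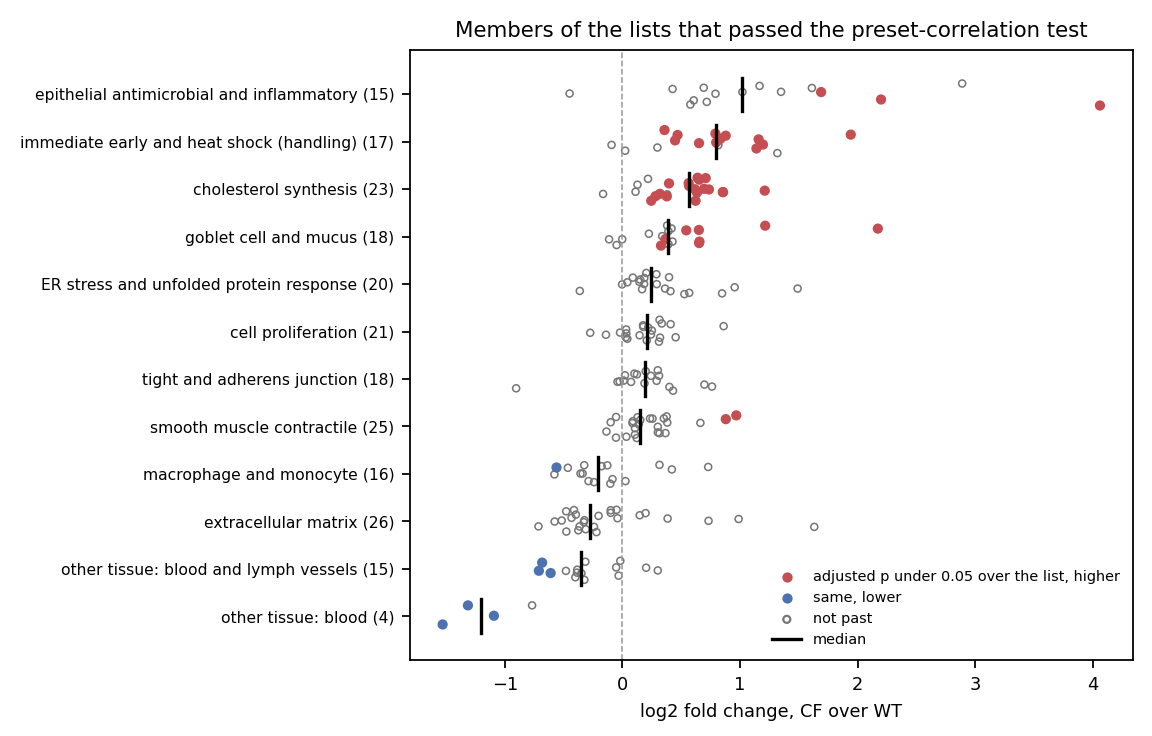
Log2 fold change of CF over WT (x axis) of each tested member of the 12 lists that passed camera's test with a preset correlation, with the number of members in brackets. Filled points passed an adjusted p of 0.05 over the list alone, and bars mark medians. Medians run from −1.20 for blood to 1.02 for epithelial antimicrobial and inflammatory genes.

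The other 21 tested lists did not pass the preset test, with adjusted p-values from 0.0843 to 0.895, but 8 of them passed it with 1 library left out. Fatty acid oxidation was lower without CF library 1 (adjusted p = 0.0244), CF library 3 (0.0427), WT library 1 (0.00148) or WT library 2 (0.00408), and Paneth cell genes were lower without CF library 3 (0.0278) or WT library 0 (0.000111). Ion and bicarbonate transport was higher without CF library 0 (0.00137), and enterocyte digestion was higher without CF library 0 (0.0192) and lower without CF library 1 (0.0201). Without WT library 3, enteric neuron and glia genes were lower (0.0330) and genes of B and plasma cells (0.0444) and of oxidative phosphorylation (0.0391) higher, and pancreas genes were higher without WT library 1 (0.0412). In the ion and bicarbonate transport list, Scnn1a, a subunit of the epithelial sodium channel, rose when adjusted over the list alone (13.8 ± 2.19 CPM against 8.40 ± 1.249 CPM, log2 fold change 0.72, SE 0.16). The abundant member Clca4 did not pass, at 2750 ± 998 CPM in CF and 1539 ± 353 CPM in WT. Enterocyte digestion genes did not differ as a list (16 of 30 with higher means), and Apoa1 and Apoa4 had log2 fold changes of 0.09 (SE 0.32) and −0.28 (SE 0.41). The suckling-type genes Lct and Plb1 and the weaned-type gene Mgam had log2 fold changes of −0.50 (SE 0.39), −1.14 (SE 0.63) and −0.15 (SE 0.23). The enteroendocrine, neuron and glia, and stem cell lists did not pass either, and their abundant members included Chgb (log2 fold change −0.02, SE 0.16), Gcg (0.06, SE 0.12) and Olfm4 (0.29, SE 0.12). The lists of interferon response, T and NK cells, B and plasma cells, fatty acid oxidation, bile acid handling, xenobiotic metabolism, oxidative phosphorylation, circadian clock and fat also did not pass, nor did those of pancreas, neutrophils and eosinophils, mast cells, Paneth cells and proximal small intestine.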

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

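The tests of Asb15, of the immediate early genes and of CF library 0 below were chosen after the results were seen. A screen of 262 groups of 4 values, each the values of 1 gene or library measure within CF or WT, marked a library where it lay far from the other 3 by Dixon's ratio at the 5% level. It marked 15 values, where about 1 in 20 groups, or 13.1, would be marked by chance, so chance alone gives nearly as many.

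In CF library 0 the screen marked Vip at 68.5 CPM (others 48.0 to 51.3), Chgb at 153 CPM (109 to 115), Duoxa2 at 56.4 CPM (39.5 to 41.7) and Tpm1 at 1077 CPM (1267 to 1298). In WT library 0 it marked Duox2 at 20.2 CPM (56.8 to 60.5), Duoxa2 at 2.98 CPM (11.2 to 12.7), Egr1 at 27.7 CPM (15.3 to 15.6), Defa9 at 173 CPM (380 to 422) and Ncf1 at 11.02 CPM (15.2 to 15.8). The 10 largest loci of that library held 15.7% of its fragments (others 18.0% to 18.3%). Myh11 was at 1301 CPM in WT library 3 (2050 to 2102). The pancreatic gene Ctrb1 was at 34.9 CPM in CF library 2 (0 to 0.549) and at 9.23 CPM in WT library 1 (0 to 0.605). A mitochondrial RNA locus, XLOC_050583, held 1.75% of fragments in CF library 2 (0.0538% to 0.0585%) and 2.29% in WT library 2 (0.0492% to 0.0905%).

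Asb15 was nearly absent in CF and lies 8.75 Mb from Cftr. The 10 nearest tested loci had a median log2 fold change of −0.37 (range −1.04 to 0.19), which argues against a loss of fragments over the whole neighbourhood, although 8 were lower in CF and 3 of these (Iqub, Gpr37 and XLOC_035700, all under 2 CPM) passed an unadjusted p of 0.05. Loci within 20 Mb of Cftr passed an unadjusted p of 0.05 in 18.8% of 154 cases against 15.1% elsewhere (odds ratio 1.30, 95% interval 0.837 to 1.97, Fisher's exact p = 0.213), so a haplotype around Cftr that differs between the groups was neither shown nor excluded. Of the 5 falls, 2 were on chromosome 4, which holds 5.76% of tested loci, and the second, XLOC_033648, lies 24.7 Mb from Cftr. A variant in Asb15 itself and an effect of the CF genotype both stay open as untested.

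Most immediate early genes had higher means in CF, as stress or delay while tissue was collected could cause. The 4 heat shock members had a median log2 fold change of 0.47 (SD 0.60) against 0.82 for the 13 other members, which could not tell handling from other causes. The CF genotype stays open as untested, as does the order in which the tissues were taken.

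CF library 0 was low in enterocyte genes, with the list's 30 members on average −1.29 log2 units from the other CF libraries. The 95% interval over these genes (−1.50 to −1.08) leaves out the spread between libraries. By library, the enterocyte score of CF library 0 (−1.03) lay below the −0.15 to 0.48 of all other libraries. Vessel genes (0.46), macrophage genes (0.32), extracellular matrix genes (0.29) and neuron and glia genes (0.29) were higher there. So were antimicrobial and inflammatory genes (1.10), proliferation genes (0.42) and stem cell genes (0.17), while T and NK cell genes (0.07) hardly differed. These are some of the tested lists. A loss of villus epithelium predicts higher vessel, macrophage, matrix, neuron and smooth muscle values, but smooth muscle genes were lower (−0.27). Only WT library 3 (−0.52) had a lower smooth muscle score than that library (−0.08), and such a loss stays open. This reading by library replaced, after the result was seen, a 95% interval over the genes (−0.42 to −0.13) that argued against the loss but left out the spread between libraries. Its depth of 20.5 M fragments lay within the 18.6 to 20.9 M of the other 3, which argues against depth, and no biological explanation inside the CF group was tested.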

How the results depend on the processing

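The comparison has 4 libraries per group, and 1 library changed its counts up to several-fold. The counts of splits by called loci and by called lists were planned before their results were seen. The splits by mean difference per list were not part of that plan. The block, the 2 other added settings and the prior degrees of freedom were chosen after the results were seen. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave 28 called loci (highest other 4). In 24 splits at least 12 lists were called (median of the others 14, highest 20), so as many list calls with the preset correlation arise when the libraries are grouped at random. Per list, the real split gave the largest mean difference of all 35 for 5 of 33 lists, where 0.943 would by chance: cholesterol synthesis, immediate early and heat shock, blood, epithelial antimicrobial and inflammatory, and neutrophil and eosinophil. The last 2 share S100a9, and all lists use the same 8 libraries, so these 5 are not independent results. A model with sex was not run, as the Y-linked loci showed no split, nor a block on the titles' numbers, which the table does not carry.

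The main comparison called 28 loci, 23 higher and 5 lower. With no filter on low counts it called 553 loci (396 higher, 157 lower), all 28 among them. The median prior degrees of freedom was 137 there and 4.53 with the filter, so the unfiltered test shrank variances far more. DESeq2, which tested 40004 loci without the main filter, called 566 (406 higher, 160 lower). On the 16941 loci of the main test limma-voom called 17 (15 higher, 2 lower). On 14515 loci with a mean FPKM of at least 1, limma on log2(FPKM + 1) called 13 (12 higher, 1 lower). On log2(FPKM + 0.1) it called 6 (6 higher, 0 lower). For DESeq2 and the FPKM values the loci and the test changed together, and which of them moved the count was not tested. An adjusted p under 0.01 left 5 loci (4 higher, 1 lower), a 2-fold minimum 17 (13 higher) and an unadjusted p under 0.05 gave 2566 (1345 higher, 1221 lower). Scaling by RLE gave 28 and by upper quartile 23. Leaving out both libraries numbered 2 gave 13 loci (11 higher, 2 lower), without Vip (adjusted p = 0.0909), Etv5 (0.0909), Fam83e (0.108) and Hba-a2 (0.140), and leaving out the mitochondrial chromosome 27.

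Leaving out 1 library moved the called loci from 5 (without WT library 1) to 136 (without CF library 0), the higher ones from 4 to 118 and the lower ones from 1 to 18. The enterocyte list was called higher without CF library 0 (adjusted p = 0.0192) and had an adjusted p of up to 0.775 without WT library 3, against lower with no call in the main test. Cftr moved from −0.06 to 0.10 and was never called. The cause was not tested. Lists called numbered 12, and were 0 with an estimated correlation and 3 with directional fry. Those 3 were immediate early and heat shock (adjusted p = 0.0107), blood (0.0282) and cholesterol synthesis (0.0400). Goblet cell genes (0.0811) and antimicrobial genes (0.143) did not pass directional fry. Mixed fry, which lets members move in either direction, called 11 lists.

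With the replicate block on the table's own numbers 11 loci were called (9 higher, 2 lower), 8 of them among the 28. B3gnt3 (adjusted p = 0.0514), Stom (0.0514), Etv5 (0.0503), Avpi1 (0.0682), Fam83e (0.0523) and Hba-a2 (0.0816) were not called there. Deviations of same-numbered libraries correlated at r = 0.07, −0.11, 0.16 and −0.01, and 4 of 8 libraries correlated best with their own number in the other group, where 2 would by chance. Not every pair deviated together, so the numbers were not taken to pair the libraries. The libraries numbered 2 shared a high share of XLOC_050583 (1.75% and 2.29%), and whether they were prepared together was not tested.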

Other observations

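The test of the sugar-chain genes below was chosen after St6galnac6 and B3gnt3 were seen among the called loci. Within lists that did not pass as a whole, some members moved in opposite directions. Among Paneth cell genes, the defensin genes Defa24 (447 ± 84.2 CPM in CF, 1028 ± 351 CPM in WT, log2 fold change −1.20), Defa9 (−1.08) and Defa8 (−0.95) and the lysozyme gene Lyz2 (−0.56) fell when adjusted over the list alone. Mptx1, a pentraxin of the same cells, rose over the list alone (30.2 ± 25.6 CPM against 1.35 ± 0.572 CPM, 4.47). Defa8 and Defa9 share a span in the table. The stem cell gene Lgr5 fell over the list alone (8.16 CPM against 14.2 CPM, log2 fold change −0.79) and Prom1 rose (0.59). Of 2 duodenal iron genes, the iron transporter gene Slc11a2 rose over its list alone (0.69) and the ferric reductase gene Cybrd1 fell (−0.93). Among mast cell and type 2 immune genes Mcpt3 (1.52), Cma1 (1.20) and Il33 (0.95) rose over the list alone, as did Csf3r among neutrophil genes (2.52, and 1.87 without CF library 0).

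Genes that build sugar chains mostly had higher means in CF. A family of 107 tested loci (102 genes) of glycosyltransferases and sugar nucleotide enzymes was set by a name pattern. Without the 3 called members, the other 104 loci gave p = 0.0198 by camera with an estimated correlation, the lowest p in an exact count over all 35 splits of the libraries (lowest other 0.0517). With 1 locus per gene the 99 left gave p = 0.0252, again the lowest in an exact count over the splits (lowest other 0.0521). Of these 99 genes 67 had higher means in CF, the median log2 fold change was 0.12, and at an unadjusted p of 0.05, 26 were higher and 1 lower. Both camera p-values are unadjusted, and the family was chosen from calls of the real split, so the count of splits favours it. The same test gave unadjusted p-values of 0.0055 for immediate early genes, 0.0225 for blood, 0.0381 for cholesterol synthesis and 0.0459 for antimicrobial genes. None of these lists passed after adjustment. Members of the family near the threshold included Slc35a2, the UDP-galactose transporter gene (72.4 CPM against 45.4 CPM, log2 fold change 0.67) and B4galnt3 (1.54). The name pattern was not limited to genes of mucin sugar chains. Its 4 members from the fixed goblet cell list were Galnt12, Gcnt3, B3gnt6 and St6galnac1, and none was called. Their log2 fold changes were 0.33 (SE 0.10), 0.39 (SE 0.21), 0.34 (SE 0.23) and −0.11 (SE 0.56). One hypothesis, not tested here, is that CF epithelium makes more, or differently capped, mucin sugar chains, possibly under Creb3l1 and Spdef. It includes more transcript of the locus matched to Muc2. It could be tested by mass spectrometry of O-glycans from Muc2 purified from both genotypes, and by counting goblet cells, since more goblet cells could give the same values.

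A second hypothesis concerns cholesterol synthesis, whose mean difference was the largest of 35 splits. If fat and bile acid uptake are poor in CF, the epithelium could respond through the sterol sensor. Camera with the preset correlation did not call ileal bile acid handling (6 of 9 tested members with higher means in CF, adjusted p = 0.644). Nor did it call enterocyte digestion and absorption (16 of 30 higher, adjusted p = 0.481), and uptake itself was not measured. The cholesterol list was not called with an estimated correlation (adjusted p = 0.379), and its score in CF library 0 (−0.09) was the lowest of the CF libraries. Giving WT rats a bile acid binder, or CF rats bile acids, and measuring the same genes would test it.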
